A study of Mus musculus with 2 samples.

How the data were processed

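Long-term haematopoietic stem cells (LT-HSC, the bone marrow cells that can rebuild the blood system over a long period) of mice lacking WASH and of control mice were profiled on a NimbleGen expression array for mouse. Per the labels, marrow was taken from femurs, LT-HSC were purified by flow cytometry, total RNA was extracted with a column kit and labelled with Cy3, and the array vendor did the labelling. Each genotype had 1 array, so 2 arrays were compared in all. No replicate spread, standard error or p-value can be had from this design.

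The authors deposited, for each array, 1 intensity per sequence on a linear scale. Per the submitters' processing notes these values came from RMA (robust multi-array average, which corrects background, normalizes arrays to each other and summarises the probes of a sequence); its version is not given in the sources used here. Per the file headers and columns, 44155 of the 44170 sequences were summarised from 3 probes and 15 from fewer, and sequence coordinates were on the mouse build MM9. The authors' series table held 34219 of these sequences, and its values differed from the array values by at most 0.0412 intensity units, so it served as an alternative with fewer sequences. RMA pulls the distributions of arrays together, so a shift of most genes in one direction would not be visible in these values.

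Intensities were turned into log2 values without further scaling, and the difference was taken as knockout minus control. Gene names came from the files and were updated through the RefSeq gene table: 21583 gene identifiers matched and 3302 symbols were updated. Of the sequences, 41886 carried a gene symbol and 2284 did not. A gene with several sequences was represented by the one with the highest mean log2 value, which left 24203 genes, 10194 of them with several sequences and 14009 with 1. A gene was in the detected range when the higher of its values lay above the median of its own array (percentile 50), which held for 16253 genes (67.2%). The 5000 probes of random sequence on each array gave a background level of 71.3 on the control array and 75.7 on the knockout array. For a named gene at or below this level on 1 array, that array's level was put in place of the value and the fold of its brightest sequence is given as a bound ("at least"), a choice made after seeing the data; counts and list medians kept the values as they were. The number of arrays, and for dim genes the closeness to this background, limits the precision.

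In place of a test, genes were counted at a fixed size of at least 2-fold (a log2 difference of 1). Olfactory receptor genes, presumed silent in these cells, gave the rate of such differences without expression. Separate sequences of 1 gene gave a spread within the arrays, which covers probe noise and differences between transcripts but no difference between animals. A total of 32 gene lists was fixed before the data were examined. The median difference of each list was placed among the medians of 10000 random lists of the same size, matched on mean log2 value in 10 bins. A list was said to stand apart at percentile 2.5 or lower, or 97.5 or higher. Lists with fewer than 5 genes in the detected range were not scored. These percentiles describe the 2 libraries and are no p-values. Of 31 scored lists, 1.55 would stand apart by chance.

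Genes were named by a rule fixed before the data were examined: the WASH complex genes and Myc; the 12 most positive and 12 most negative differences among genes above percentile 75 of their array whose sequences all differed in the same direction, leaving out predicted or clone symbols and chemosensory receptors; up to 4 genes per list at 2-fold or more, or up to 2 where none reached it; and genes of LT-HSC sort markers and common reference genes. Other list members are given as examples of their list and were chosen after their values were seen. Flt3, Actb and Washc4 were not analysed here, and some genes that the rule names are not reported here.

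The steps were tested on simulated data for the knockout against control comparison, with noise of 0.65 (log2 SD) on 16130 genes. Of 97 genes changed 2-fold, 49 (50.5%) were counted, and of 100 genes changed 4-fold, 95 (95.0%) were counted. Of 15905 unchanged genes, 2210 (13.9%) also passed the 2-fold size. That share follows from the noise chosen, which was close to the spread between sequences of 1 gene (0.657). Of 200 unchanged lists, 11 (5.50%) stood apart. The noise was drawn independently and these lists held random genes, so this rate does not cover genes that vary together.

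Alternatives planned before the data were examined were the series table, centring of the arrays, quantile normalization, loess removal of an intensity trend (span 0.3), an offset before the log, the mean or the dimmest sequence of a gene, other filters on dim genes, sizes of 1.5-fold and 3-fold, the mean of a list, unmatched random lists and 20 bins. Added after seeing the data were a filter at 2 times the random-sequence level, a count of genes with every detected sequence at 2-fold, lists without erythroid and granulocyte genes, and lists without shared genes. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.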

Results

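Gene expression was measured in sorted LT-HSC from C57/BL6 mice, with 1 array for the WASH knockout and 1 for the control. The arrays had similar distributions, with median intensities of 137 on the control array and 137 on the knockout array over 44170 sequences, and upper quartiles of 328 and 329.9. The log2 values of the arrays correlated at r = 0.922 across sequences, which are not independent replicates. With no replicates, no difference given here was tested against variation between animals.

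Washc1, which encodes the WASH protein and is the targeted gene, had an intensity of 119 on the control array and 107 on the knockout array, a log2 difference of -0.15. Its single sequence (chromosome 17, 66460972 to 66468796, MM9) was not in the detected range on either array, at 1.67 and 1.42 times the random-sequence level. Whether its probes lie in the deleted part is not known here, so this value does not check the genotype labels. Among its partners, Washc2, the FAM21 subunit that links the complex to endosomes, was at 466 in the control and 151 in the knockout, a difference of -1.63 (chromosome 6, 116158123 to 116205145), and all 3 of its sequences were lower in the knockout, by -0.72 to -1.75. The actin capping subunits Capza2 and Capzb differed by -1.17 and -0.77, Capza1 by 0.27 and Washc3 by -0.07. Washc5 was not in the detected range. The 5 complex genes in the detected range had a median difference of -0.77, at percentile 1.98 of random lists, and 2 of them were at least 2-fold lower. This list no longer stood apart after quantile normalization (-0.68), after loess (-0.70) or with dim genes kept (-0.15).

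**Figure D1:**
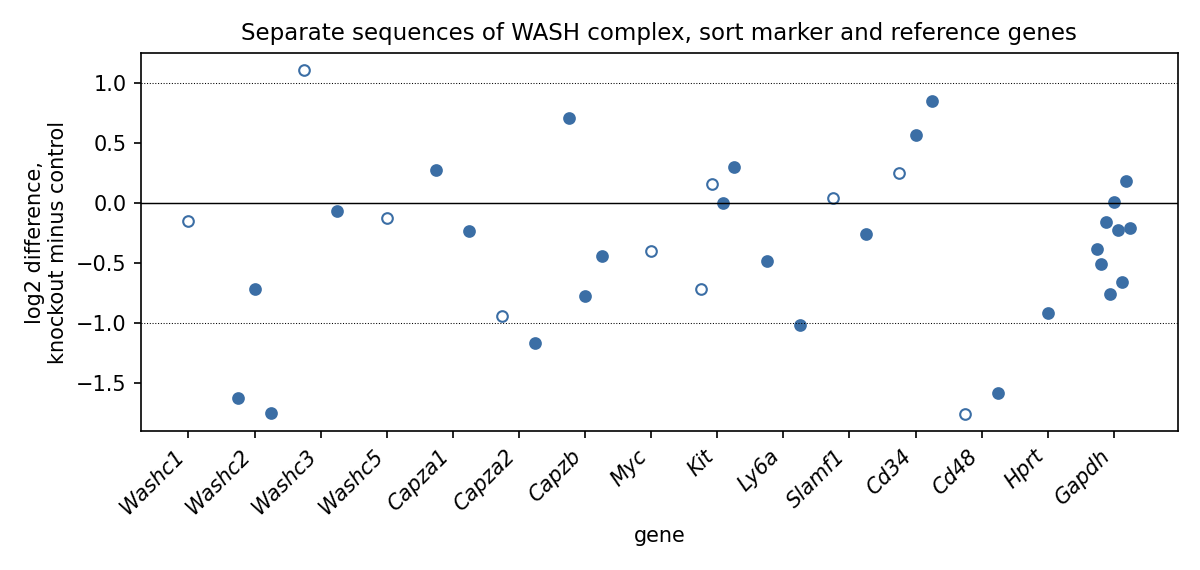
Log2 difference (knockout minus control, 1 array each, vertical axis) of every sequence of the WASH complex genes, Myc, genes of sort markers and reference genes (horizontal axis); filled points are in the detected range, open points are not, and dotted lines mark 2-fold. The 3 sequences of Washc2 lie between -1.75 and -0.72, and the 9 of Gapdh between -0.76 and 0.18.

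Across the transcriptome, 1043 genes were at least 2-fold higher and 1186 at least 2-fold lower on the knockout array, together 13.7% of the genes in the detected range. The highest differences under the naming rule were those of Msantd2 (4.25), the small nucleolar RNA Snora61 (3.53), Apol11b (3.09), the adult beta-globin gene Hbb-b1 (2.92), the cell polarity gene Scrib (2.85), Glrx5, which serves iron-sulphur cluster assembly (2.73), Prxl2a (2.69) and Tekt1 (2.68). The rule also named Tc2n, Flicr and Pdcl2, which were not above the random-sequence level on the control array and so have no measured rank; their brightest sequences were at least 6.42-fold, 4.90-fold and 4.74-fold higher in the knockout, while the other sequence of each differed by 0.79, 0.22 and 0.11. The lowest were D14Ertd426e (-3.47), the granzyme gene Gzmb (-2.64), Ptcd3 (-2.54), the focal adhesion gene Pxn (-2.45), Slfn1 (-2.42), Eef1akmt2 (-2.41), Il1f9 (-2.39), Serpinb1c (-2.35), Gstt1 (-2.32), the annexin gene Anxa1 (-2.28), Gcnt2 (-2.28) and Triap1 (-2.26). On the control array Tekt1 and Scrib were at only 1.03 and 1.19 times the random-sequence level. Ptcd3, Pxn and Eef1akmt2 were at 1.12, 1.08 and 1.31 times that level on the knockout array. The differences and ranks of these genes thus rest on a value near background. Apol11b went from 2160.2 to 18340 and all 3 of its sequences were higher, by 2.56 to 3.29. Both sequences of Anxa1 were lower, by -1.64 and -2.28. Other genes of this ranking differed far less with another of their sequences, by 1.06 for Msantd2, 0.57 for Scrib, 0.32 for Tekt1, -0.19 for Gcnt2, -0.06 for Ptcd3 and -0.001 for Eef1akmt2. Snora61, Hbb-b1, Glrx5, D14Ertd426e, Gzmb, Slfn1, Serpinb1c, Gstt1 and Triap1 had 1 sequence each, so agreement between sequences could not be checked for them.

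The rate of such differences was not above that of presumed silent genes over the detected range, where 44 of 317 olfactory receptors (13.9%) also differed at least 2-fold. Above the 75th percentile of intensity the rate was 12.8% of 9476 genes against 6.99% of 143 olfactory receptors. Across the 4962 genes with several sequences in the detected range, the differences of a pair of sequences of 1 gene correlated at Pearson r = 0.159 and Spearman rho = 0.145 (across genes, which are not independent replicates). Over the 2006 such genes above the 75th percentile, r was 0.298 and rho 0.276. Among the 4962 genes, all detected sequences were at least 2-fold higher in 33 and at least 2-fold lower in 59. The averages in 100 shuffles were 14.2 and 25.7. An offset before the log left 496 genes higher and 637 lower.

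Erythroid markers were higher on the knockout array. All 20 measured markers were in the detected range, 14 were at least 2-fold higher and none was 2-fold lower, with a median difference of 1.58 at percentile 100 of random lists. Hbb-b1 went from 5699 in the control to 43218 in the knockout (chromosome 7, 110961171 to 110962384). The alpha-globin genes Hba-a1 and Hba-a2 differed by 2.41 and 2.27, the carbonic anhydrase gene Car2 by 2.32, and the red cell membrane gene Epb42 went from 329 to 1317. Car1 and Klf1, a transcription factor of erythroid cells, were not above the random-sequence level on the control array and were at least 2.57-fold and 2.69-fold higher. Gata1 was higher by 0.38, while the spectrin gene Sptb differed by -0.58. The list stood apart in all 15 settings in which it was scored.

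Granulocyte and monocyte markers were lower on the knockout array, with a median difference of -0.76 at percentile 0.00. Of 19 markers in the detected range, 14 were lower, 4 of them at least 2-fold, and 1 (Csf1r, 1.18) was at least 2-fold higher. The calprotectin genes S100a8 and S100a9 went from 47334 to 16696 (-1.50) and from 34133 to 13043 (-1.39), and the neutrophil granule genes Lcn2 and Ngp differed by -1.65 each. These are among the brightest genes of both arrays. The 7 mast cell, basophil and eosinophil markers in the detected range had a median of -0.85 (percentile 0.140), with the eosinophil granule gene Prg2 at -1.08. That list did not stand apart with the mean of a gene's sequences (-0.33), the dimmest sequence (-0.22) or dim genes kept (-0.19).

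**Figure D2:**
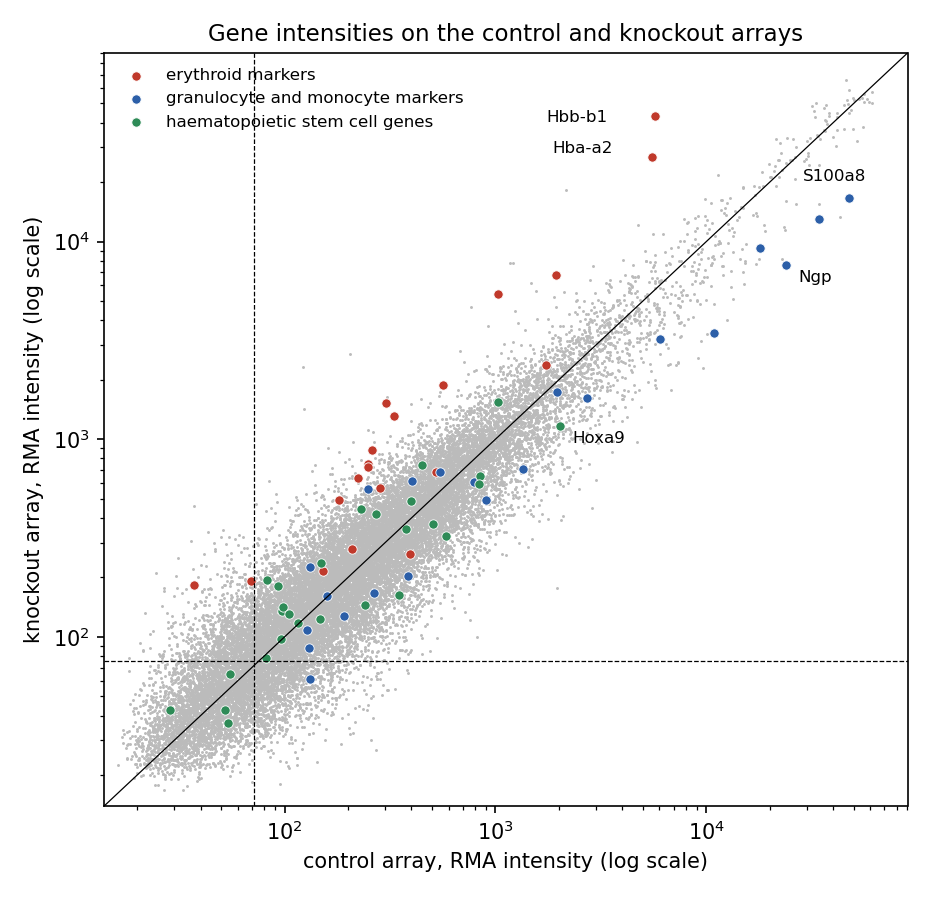
Intensity of each gene on the control array (horizontal axis) and the knockout array (vertical axis), both RMA intensities on log scales, with erythroid (red), granulocyte and monocyte (blue) and stem cell genes (green) marked; dashed lines are the random-sequence levels of 71.3 and 75.7 and the diagonal marks equal values. Hbb-b1 lies above the diagonal, at 5699 and 43218, and S100a8 lies under it, at 47334 and 16696.

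Genes of actin nucleation, protein synthesis and energy metabolism were lower together with the granulocyte markers. The list of the Arp2/3 complex, the actin nucleator that WASH activates, and of other nucleation promoting factors had a median of -0.56 at percentile 0.280, with 11 of 16 genes lower and 3 at least 2-fold lower: Actr3 (-1.58), Arpc5 (-1.30) and Actr2 (-1.11). Of 83 ribosomal protein genes, 62 were lower and the median was -0.29 (percentile 0.00), with Rps13 at -1.70. Oxidative phosphorylation genes had a median of -0.25 (percentile 0.0300), with 53 of 77 lower, among them Ndufs5 (-1.53) and Ndufb7 (-1.53), but 23 other sequences of these genes had a median of 0.07. Other sequences had medians of -0.97 for the Arp2/3 list (14 sequences), -0.22 for ribosomal protein genes (87 sequences) and -0.50 for glycolysis and hypoxia genes (28 sequences). Glycolysis and hypoxia genes had a median of -0.43 (percentile 0.690), with Pgk1 at -1.79 and Gpi1 at -1.31, and did not stand apart with dim genes kept (-0.27). Pgk1 and Hprt (-0.92) are also common reference genes, and the 9 sequences of Gapdh ranged from -0.76 to 0.18.

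The stem cell genes in the detected range did not shift as a group. Of 27 measured, 18 were in that range, 9 of them higher and 9 lower. Their median was 0.10 at percentile 63.0, beside 1.58 for erythroid and -0.76 for granulocyte and monocyte markers. Procr, Tek, Fgd5 and Tcf15 were not above the random-sequence level on either array, so a shift in them could not be seen. Prdm16, at 1.16 times the random-sequence level on the control array, was higher by 1.23, but its other sequence by only 0.10. Mecom, another zinc finger regulator of stem cells, differed by -1.10. Its 6 sequences ranged from -1.65 to 0.49, with 4 lower and 1 higher. Kit, the gene of a common LT-HSC sort marker, was at 398 in the control and 489 in the knockout (0.30), and Slamf1 at 147 and 123 (-0.26). Ly6a, which encodes Sca-1, differed by -0.49 and Cd34 by 0.57. Cd48, a marker of committed progenitors, was not above the random-sequence level on the knockout array, where its brightest sequence was at least 2.01-fold lower. The median of the stem cell genes turned to -0.24 with the series table and with the 75th percentile filter on dim genes. The progenitor list had a median of -0.38 (percentile 3.01), inside the range of random lists, and stood apart with the mean of a gene's sequences (-0.41) or with dim genes kept (-0.33). Medians of the megakaryocyte (-0.05), B lymphoid (-0.07), T and NK lymphoid (0.07), macrophage and dendritic (0.17) and stromal (-0.04) lists were also inside that range. The B lymphoid median turned to 0.54 with the series table (percentile 97.8) and to 0.57 with the mean of a gene's sequences (percentile 99.1), and stood apart in both.

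The published work on these mice concerned c-Myc in stem cell differentiation, so Myc and its targets were examined. Myc (chromosome 15, 61816895 to 61821916) was at 130 in the control and 98.6 in the knockout, a difference of -0.40, and was not in the detected range on either array. Of 36 Myc target genes in the detected range, 23 were lower and 13 higher, with a median of -0.18 at percentile 5.11, inside the range of random lists, and stood apart only with the series table (-0.27). The targets at 2-fold or more were lower for Nme2 (-1.54), Ldha (-1.22) and Eif4a1 (-1.03), and higher for the polyamine synthesis gene Odc1 (1.42) and for Rcl1 (1.21). Eif5a differed by -1.81 with its brightest sequence and by 1.41 with its dimmest, while 5 of its 6 sequences were lower. Haematopoietic transcription factor genes had a median of -0.01 (percentile 39.7), while 27 other sequences of these genes had a median of -0.49. The 4 genes at 2-fold or more were all higher, with Klf1 (at least 2.69-fold) and log2 differences of Spi1 (1.35), Lmo2 (1.13) and Tal1 (1.10). All 3 sequences of Tal1 were higher, while Klf1, Spi1 and Lmo2 had 1 sequence each. Spi1 was at only 1.08 times the random-sequence level on the control array. Proliferation genes had a median of 0.16 (percentile 80.3), with Mki67 at 1.18, Ccna2 at 1.31 and Ccnd1 at -1.42.

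**Figure D3:**
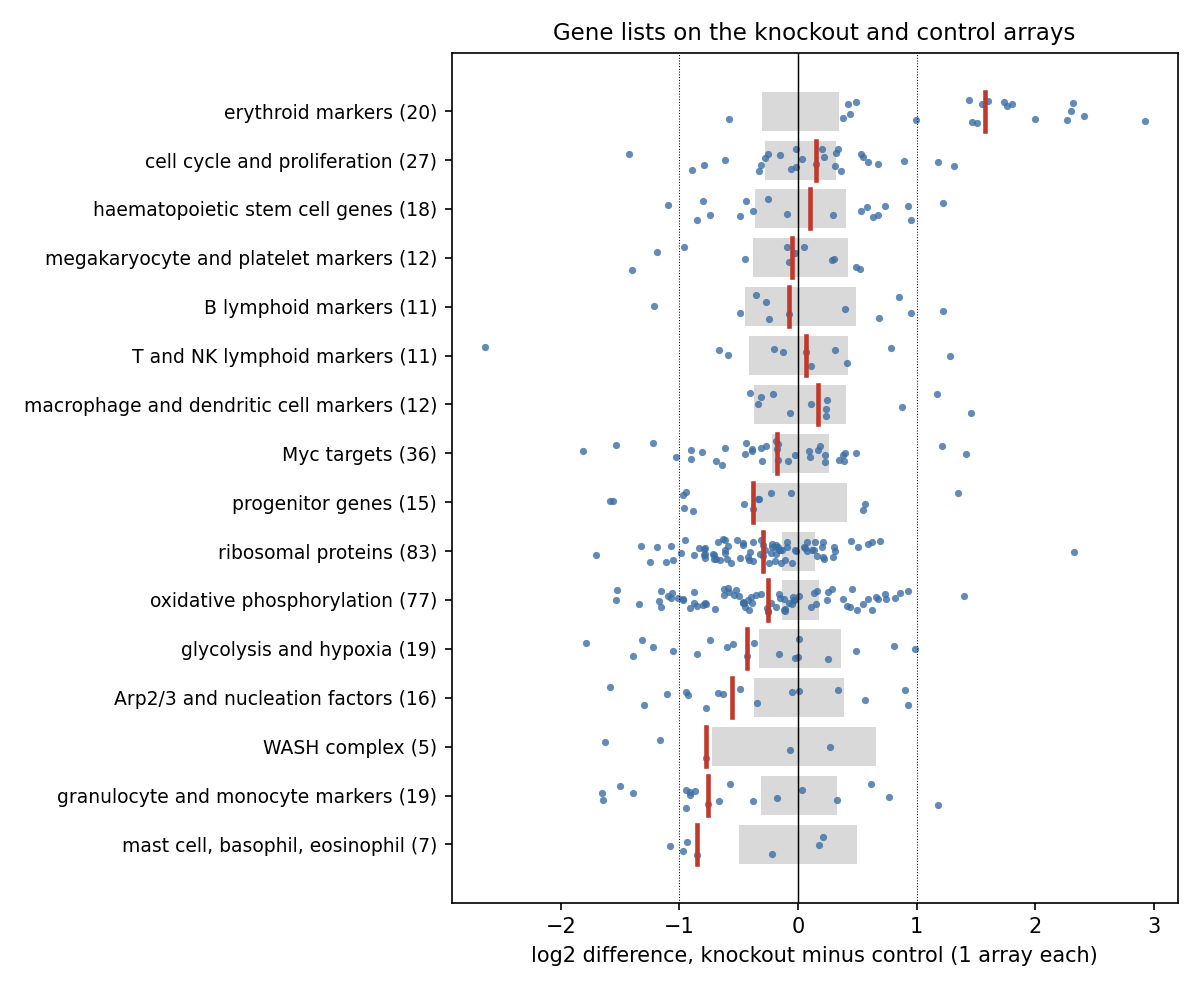
Log2 difference (knockout minus control, 1 array each, horizontal axis) of the genes in the detected range of 16 lists (points, with their number in brackets), the median of each list (red bar) and the central range of 10000 matched random lists (grey, outside which a list was said to stand apart). The erythroid median of 1.58 lies above its grey range and the granulocyte and monocyte median of -0.76 lies under its own.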

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

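Among the tests in this part, the comparison of markers of other lineages for a loss of stem cells and the readings of further genes as a test of noise were chosen after the results were seen. The rule for reading the noise tests was also settled after their values were seen: a value outside the random range counts against noise however few genes it covers, and a value inside it from fewer than 5 genes decides nothing. The erythroid and granulocyte tests both covered 4 genes. The other tests were set down before their own results were seen.

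Among sequences without a gene symbol, which entered the report's array medians and correlation but none of its gene or list comparisons, 80 in the detected range were at least 2-fold higher on the knockout array than on the control array. A further 99 were at least 2-fold lower, of 1279 such sequences in the detected range.

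Erythroid markers were higher on the knockout array by a median of 1.58. An intensity trend was argued against, since loess left the median at 1.57, and so was noise of single sequences, since 6 other sequences, of only 4 of these genes, had a median of 2.35 and 26 further erythroid genes, 1 of them also a reference gene, had 0.59 at percentile 100. Fewer stem cells in the knockout sample would raise markers of every other lineage if the other cells kept their proportions. The granulocyte and monocyte median was -0.76, which that case would not give. Fewer stem cells with a changed mixture of other cells stay open, since this comparison cannot tell. RNA of erythroid cells is a candidate source, as a hypothesis: the median of 0.59 for the further genes is what it predicts, and Hbb-b1 at 43218 is one of the brightest genes, although the LT-HSC sort should remove such cells and Slc4a1 was higher by only 0.44. An effect of the genotype on erythroid genes within the stem cells stays open and was not tested, as was a difference between individual animals or sorts, because each genotype has 1 array.

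Granulocyte and monocyte markers were lower on the knockout array by a median of -0.76. Loess left the median at -0.72, which argues against an intensity trend. The planned test of noise decided nothing, because 5 other sequences covered only 4 of these genes and their median of -0.48 lay inside the random range (percentile 12.4), where noise would place it; the 30 further neutrophil genes, read for this purpose only afterwards, had -0.87 at percentile 0.00, which noise of single sequences would not give. RNA of neutrophils, more of it in the control sample, is a candidate source, as a hypothesis: the same median of -0.87 is what it predicts and S100a8 was at 47334 and 16696, although the sort should remove neutrophils and some of these genes were higher in the knockout, namely 6 of the 30 further genes, with Il1b at 0.98, and 5 of the 19 markers, with Csf1r at 1.18, Itgam at 0.77 and Ly6c2 at 0.62. An effect of the genotype on these genes within the stem cells stays open and was not tested.

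The Arp2/3 list was lower on the knockout array by a median of -0.56, which touches the known partner of WASH. Loess left it at -0.56, and 14 other sequences of 11 of these genes had a median of -0.97, which argues against an intensity trend and against noise of single sequences. The 33 leukocyte actin genes outside the list had a median of -0.66 at percentile 0.00, with Lcp1 at -1.83 and Tmsb4x at -1.48, so the lower values may belong to leukocyte actin genes in general and were not particular to Arp2/3. A response of Arp2/3 genes to the loss of WASH stays open, and was not separated here from the lower granulocyte signal.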

How the results depend on the processing

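No paired analysis was possible because each genotype has 1 array and no difference was tested. The filter at 2 times the random-sequence level, the count over every sequence of a gene, and lists without shared or without erythroid and granulocyte genes were chosen after seeing the data. The last took no gene from the 6 lists that stood apart under it, so it says nothing about them. Leaving out shared genes likewise took none from the WASH complex and Arp2/3 lists. Centring shifts every gene alike, so it cannot change a percentile. Against 1043 genes at least 2-fold higher in the knockout and 1186 genes at least 2-fold lower in the knockout, the counts were 496 and 637 with an offset before the log, 539 and 676 with the 75th percentile filter, 3007 and 2973 at 1.5-fold, 242 and 281 at 3-fold, and 679 and 804 with the mean of a gene's sequences. Where every sequence of a gene had to differ 2-fold they were 33 and 59, over only the 4962 genes with several detected sequences. Stricter sizes and filters count fewer genes by construction. With the mean of a list in place of its median 14 lists stood apart, against 8. The Arp2/3, ribosomal and oxidative phosphorylation lists stood apart in all 16 settings. The erythroid (1.31 to 1.67) and granulocyte and monocyte lists (-0.91 to -0.55) did so in all 15 that kept them. Such counts include the run as first set and the settings that could not change a list's outcome. The WASH complex list stood apart in 8 of the 11 settings that left it enough genes, but not with quantile normalization (-0.68), loess (-0.70) or dim genes kept (-0.15). The mast cell list did not stand apart with the mean (-0.33) or dimmest (-0.22) sequence or with dim genes kept (-0.19), nor the glycolysis list with dim genes kept (-0.27). The Myc target median was -0.27 with the series table, where it stood apart, and -0.022 with the dimmest sequence. The stem cell median was -0.24 with the series table and with the 75th percentile filter, -0.10 with the filter at 2 times the random-sequence level, 0.30 with the dimmest sequence and 0.41 without shared genes. Progenitor genes stood apart with the mean of a gene's sequences (-0.41), the mean of the list (-0.41), dim genes kept (-0.33) and without shared genes (-0.67). Among named genes at 2-fold or more, the dimmest sequence turned the direction for Bank1 (0.048), Baz1a (0.12), Bcl2l1 (-0.46), Canx (0.50), Eea1 (0.41), Eif5a (1.41), H2-Aa (-0.67), Kdr (-1.23), Ndufb2 (0.76), Pfkp (1.24, and 0.008 with the mean of its sequences), Rpl24 (0.95) and Uvrag (-0.001). Of 122 named genes, 29 others kept their direction or were under 2-fold but moved by more than the spread within genes (0.657) with the dimmest sequence, and 25 with the mean of sequences. Named genes with 1 sequence, such as Hbb-b1 and S100a8, could not change in these settings. Shares of the 122 therefore understate how often genes with several sequences changed. The cause of these changes was not tested. Centring, quantile normalization and loess turned no named gene at 2-fold or more. Signal limits the dim genes: the array medians were 1.92 and 1.82 times the random-sequence level.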

Other observations

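Genes of endosomal sorting and of several signalling pathways had medians on the lower side on the knockout array. In the retromer and endosomal sorting list, 6 of 17 genes in the detected range were at least 2-fold lower and none was 2-fold higher, among them the sorting nexin genes Snx27 (-1.34), Snx2 (-1.31) and Snx6 (-1.23), with a median of -0.26 at percentile 7.98. That list stood apart with the series table (-0.80, percentile 0.120), the dimmest sequence of a gene (-0.54, percentile 1.64) and the mean of the list (-0.51, percentile 0.120). TGF-beta, Notch and Wnt genes had a median of -0.32 (percentile 5.20), with 4 at least 2-fold lower, including the Notch ligand gene Jag1 (-1.48). Smad3 and Tgfb1 were not above the random-sequence level on the knockout array and were at least 2.06-fold and 2.99-fold lower there. The TGF-beta, Notch and Wnt list stood apart with the mean of the list (-0.48, percentile 0.40) and without shared genes (-0.60, percentile 0.380), while 12 other sequences of these genes had a median of 0.27. Interferon response genes had -0.19 (percentile 12.7), with Ifit1 at -1.14, Ifitm3 at -1.08 and Rsad2 at 1.12, and stood apart in none of 16 settings. Immediate early and heat shock genes had -0.16 (percentile 15), with Fosb at -1.27, Zfp36 at -1.19, and 9 genes higher and 9 lower. That list stood apart with the mean of a gene's sequences (-0.36, percentile 1.16). Its median turned to 0.03 with the 75th percentile filter and without shared genes.

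Medians of the remaining lists lay inside the random range as first set, and several left it in other settings. They were -0.18 for proteasome subunits (percentile 5.40), with Psma6 at -1.51 and Psmb10 at 1.24, and -0.17 for NURF and related chromatin remodelling subunits (percentile 17.8), with Smarca5 at 1.03. Housekeeping genes had -0.18 (percentile 13.9), the unfolded protein response -0.15 (percentile 23.3), p53 targets and apoptosis regulators -0.11 (percentile 25.8) and adhesion and migration genes -0.05 (percentile 34.5). Quiescence genes had 0.08 (percentile 62.3), with Nr4a1 at -1.11. Autophagy and lysosome genes had 0.27 (percentile 91.8), and olfactory receptors 0.12 (percentile 96.8). Housekeeping genes stood apart with the series table (-0.49, percentile 0.780), the mean of the list (-0.46, percentile 0.560) and without shared genes (-0.49, percentile 1.68). With the 75th percentile filter the unfolded protein response (-0.58, percentile 0.960) and the p53 list (-0.46, percentile 2.23) stood apart. Proteasome subunits did with dim genes kept (-0.23, percentile 1.41) and with the mean of the list (-0.25, percentile 1.77). Olfactory receptors, presumed silent, stood apart as higher with the series table (0.20, percentile 99.95), the mean of a gene's sequences (0.12, percentile 99.6), the mean of the list (0.11, percentile 99.1) and unmatched random lists (0.12, percentile 98.7). The sex-linked list had 4 genes in the detected range and was not scored. Its median was 0.43, with Kdm5d at 0.61, Xist at 0.46, Uty at 0.39 and Eif2s3y at -0.89. Of the 5 sequences of Kdm5d, however, 4 were lower, down to -1.22, and only 1 was higher. With the mean of a gene's sequences the list median was -0.09, over 3 genes. In 5 lists the mean and the median differed in sign, namely the transcription factor, quiescence, B lymphoid, T and NK lymphoid and p53 lists.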
